A study of Mus musculus with 2 samples.

How the data were processed

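RNA was isolated with the RNeasy kit from micro-dissected bladder urothelium, per the labels' protocols, and 1 sample was listed for each of the genotypes, wild type and urothelium-specific Eed knockout. Groups were taken from the genotype labels. The submitters' processing notes name STAR, a spliced read aligner, and edgeR, with no versions; the genome build and the counting tool were not given in the sources used here. Of 18511 gene identifiers found in the GENCODE M21 annotation of the GRCm38 mouse assembly, 95.7% had both ends within 5000 bases of it and 67.0% had identical coordinates. Coordinates are printed as the deposited table gives them. Gene names were used as the table pairs them with identifiers; 25 names had been turned into dates and were not named.

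The deposited table gave, per its column headers, 1 signal column per genotype, along with a log2 fold change, a p-value and an adjusted p-value per gene from the authors. The unit of the signal columns was worked out from the values: gene read counts divided by a size factor. In the wild-type column 100% of non-zero values were whole multiples of 1.05, the value of 1 read, within 0.001 read, which gives a size factor of 0.955. The deposited knockout signal had steps of 0.474 and 0.487, the values of 1 read in a mean of 2 libraries with size factors of 1.05 and 1.03. Exactly 1 pair of whole read numbers gave the deposited value for 18546 genes (99.5%). For 92 genes, all with a knockout value of at least 21747 and together 21.0% of that column's total, several pairs fitted and no value per library was used. In simulated means of 2 libraries, 98.4% of genes had 1 pair, and 100% of those pairs were right. The recovered libraries differed by far more than counting error, with a median chi-square per gene of 35.6 over 13562 genes with at least 50 reads, where counting error alone gives 0.455, so they were not 1 library counted again. The order of the libraries, 1 and 2, is arbitrary.

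DESeq2 with a normal prior on fold changes, run on the recovered reads as 2 libraries against 1 with the recovered size factors, gave log2 fold changes within 0.00629 of the deposited ones across 18546 genes, with a median absolute difference of 0.000244. Without the prior, the Pearson r across genes was 0.509. The submitters' notes name edgeR, and which tool made the deposited values is known only through this match.

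The design fixed before the data were examined expected raw counts. Because the table held normalised counts, the fallback written in that design was used: log2 of the ratio of knockout to wild-type values, each plus a pseudocount of 1, for genes with a summed value of at least 10, with at least 2-fold as the size rule and no test. This log2 scale understates the change of low genes. Direction always means knockout-labelled over wild-type-labelled. For each of 34 gene lists, the median log2 ratio minus the median of all genes was placed among 10000 random lists of the same size matched on mean expression in 20 bins, and a list was said to stand apart in the lowest or highest 2.5%. Members were counted as higher or lower from 1.5-fold. Libraries with this design were simulated on 18638 genes, with edgeR's common dispersion of 0.491 (described below) for every gene. Changed genes and the raised list were drawn from genes with a mean of at least 50 normalised counts. The size rule found 77.5% of genes changed 4-fold and passed 45.5% of unchanged genes. The latter is above the 35.7% of all genes that passed in the data, so the simulation overstated the spread. Of 100 unchanged lists 1 stood apart, and a list of 25 genes raised 2-fold reached percentile 98.9. Genes were simulated independently of each other, so these list figures do not hold for lists of co-regulated genes; 17 of the 34 lists stood apart between the knockout-labelled libraries.

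The lists covered PRC2 subunits, Hox genes, other developmental transcription factors, cyclin-dependent kinase inhibitors, proliferation, superficial urothelium, basal urothelium, squamous differentiation, junctions, cytokines, chemokines, NF-kB targets, bacterial sensing, antimicrobial and acute-phase proteins, interferon-stimulated genes, MHC class II, prostaglandins, epithelial-mesenchymal transition, sterol synthesis, hypoxia and glycolysis, and stress genes. They also covered neutrophils, monocytes and macrophages, dendritic cells, lymphocytes, mast cells and eosinophils, fibroblasts, smooth muscle, endothelium, nerve and glia, erythrocytes, adipocytes, mitochondrially encoded genes and sex-linked genes.

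Genes named in the text follow a rule written in advance: Eed, the 15 protein-coding genes with the largest ratio in each direction among those with at least 100 normalised counts on the higher side, up to 4 members of each list (6 where it stands apart) with the largest ratios among those with at least 20, each list's most abundant members where no difference is described, and the 5 most abundant genes of each column. Genes outside this rule are said to have been chosen after their values were seen, or were called by edgeR or in the authors' table.

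The recovered reads were tested with edgeR 4.0.16 (quasi-likelihood test, TMM normalisation, Benjamini-Hochberg adjustment) as 2 knockout-labelled libraries against 1 wild-type-labelled library, an analysis added after the libraries had been found in the data. The lone wild-type library is assumed to vary as the knockout-labelled ones do. The common dispersion was 0.491, a biological coefficient of variation of 0.70. Counts were simulated on 18546 genes with the trended dispersion of the data, and the changed genes were drawn from those with a mean of at least 50 reads. There edgeR called 5 of 100 genes changed 4-fold, 53 of 100 changed 16-fold and 77 of 100 changed 64-fold, and 0 unchanged genes. Power for genes with fewer reads was not simulated. Genes were drawn independently, without shifts shared by many genes such as the trend on gene length, so the 0 is not the false call rate in the data. An earlier simulation with the common dispersion for every gene recovered none of the genes changed 4-fold or 16-fold, so the power depends on the dispersion assumed. Tools were R 4.3.3, DESeq2 1.42.0, limma 3.58.1, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

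Alternatives fixed in advance were other scalings (total counts, TMM, upper quartile, median of ratios, total counts without the 20 most abundant genes), a pseudocount of 5, thinning of reads, the authors' log2 fold changes, a minimum sum of 1 or 50, protein-coding genes only, and for lists, unmatched random lists, matching on gene length and leaving out shared members. Added after seeing the data were each knockout-labelled library alone, the mean over the genes with recovered reads, list percentiles between the knockout-labelled libraries, edgeR and DESeq2 on recovered reads, both libraries past the size rule, and removal of the trend on gene length.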

Results

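RNA sequencing compared the bladder mucosa of a mouse sample labelled wild type with that of a sample labelled as lacking Eed in the urothelium, the epithelium that lines the bladder. Eed is a core subunit of Polycomb repressive complex 2 (PRC2), which silences genes by methylating histone H3. There was 1 labelled sample per genotype, both described as female mucosa taken on day 1 and both labelled as severe or super infection. The sample titles add CPP, an abbreviation the labels do not spell out, to urinary tract infection, and the series design names the uropathogenic Escherichia coli strain UTI89 as the inoculum. Mice given saline were not analysed here. The series title frames the question as how chromatin remodelling by PRC2 bears on inflammation and on how severe the infection becomes.

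The deposited table listed 18638 genes with 1 column of normalised read counts per genotype. The wild-type column held the whole reads of 1 library, 26453150 in total. The Eed knockout column was the mean of 2 libraries, although the labels list 1 knockout sample, and the reads of each could be recovered for 18546 genes. Over those genes the libraries held 20732787 reads (knockout-labelled library 1), 18649917 reads (knockout-labelled library 2) and 19914647 reads (wild-type-labelled library). The labels do not say whether the knockout-labelled libraries came from separate mice, so p-values measure only the spread between these libraries, which may be technical. The wild-type-labelled group had a single library, and every difference compares these libraries, not the genotypes. Intervals and zero-count floors cover counting error only.

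The targeted gene was examined first, as a check on the labels. Eed (ENSMUSG00000030619, chromosome 7, 89954656 to 89980983) stood at 992 normalised counts in the library labelled wild type and 825 in the mean of the libraries labelled Eed knockout, a ratio of 0.832 with a 95% exact counting interval of 0.766 to 0.899. Knockout-labelled library 1 had 679 normalised counts (exact Poisson interval 630 to 731) and library 2 had 971 (911 to 1033), against 930 to 1057 around the wild-type value. A difference between library 2 and wild type was not detectable at this depth. The log2 ratio of Eed, −0.27, was −0.054 with scaling to total counts, −0.068 with scaling without the 20 most abundant genes and −0.0080 with the trend on gene length (described later) removed (the interval does not cover these choices). Other PRC2 genes were at or above the wild-type level in the mean: Ezh2, the catalytic subunit, at 1569.6 against 1350.2, Suz12, a core scaffold subunit, at 1346 against 1009, and Ezh1, the alternative catalytic subunit, at 1639 against 887. Ezh2 was lower than wild type in library 1 (1089.6) and higher in library 2 (2049.7). Counts over a whole gene include exons outside any deleted part and cells other than urothelium, so the Eed values neither verify nor refute the genotype labels, and the libraries are called by their labels throughout. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, Eed was not called (adjusted p = 0.906).

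**Figure D1:**
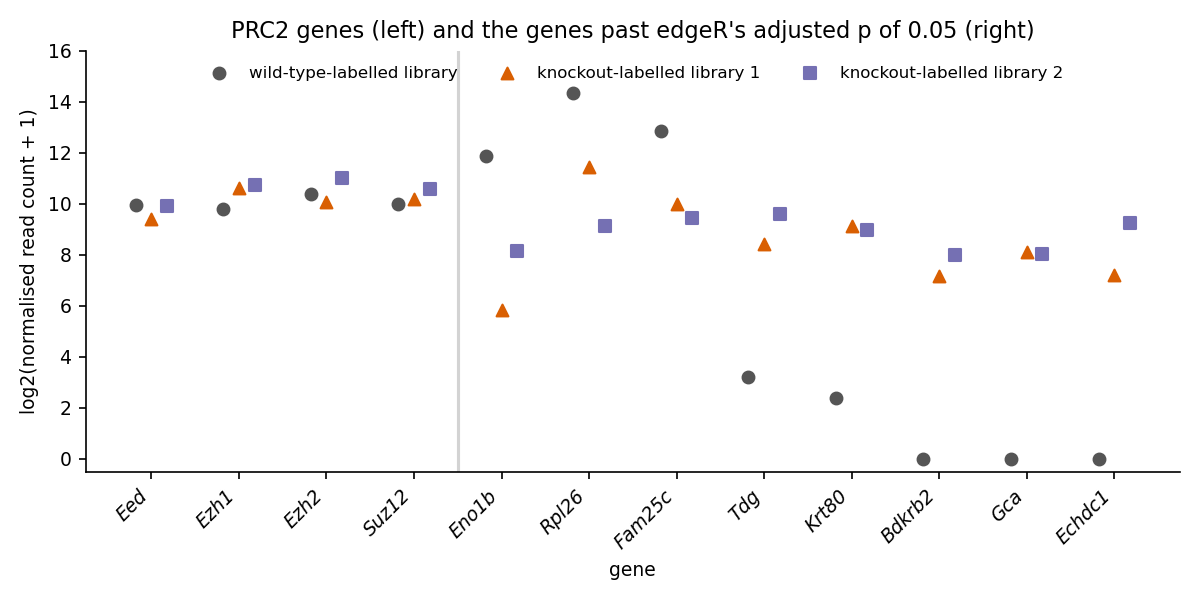
Normalised read counts, as log2 of the count plus 1 on the vertical axis, of 4 PRC2 genes (left of the grey line) and of the 8 genes past an adjusted p of 0.05 in edgeR's test (right), with 1 point per library. Eed was at 992 normalised counts in the wild-type-labelled library and at 679 and 971 in the knockout-labelled libraries, whereas Bdkrb2, Gca and Echdc1 had 0 reads in the wild-type-labelled library.

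Across the transcriptome, the strongest differences were in genes with few or no reads on one side. Krt80, an epithelial keratin (ENSMUSG00000037185, chromosome 15, 101349571 to 101370125), rose from 4.19 normalised counts in the wild-type-labelled library to 557 and 505 in the knockout-labelled libraries. Tdg, a DNA glycosylase that excises mismatched and oxidised bases (ENSMUSG00000034674, chromosome 10, 82629828 to 82650799), rose from 8.38 to 341 and 768. Echdc1, an enzyme that removes aberrant acyl-CoA products (ENSMUSG00000019883, chromosome 10, 29313166 to 29346661), Gca, the calcium-binding protein grancalcin (ENSMUSG00000026893, chromosome 2, 62664285 to 62694109), and Bdkrb2, the bradykinin B2 receptor (ENSMUSG00000021070, chromosome 12, 105563172 to 105593071), had 0 reads in the wild-type-labelled library and 148 and 613, 275 and 258, and 145 and 257 normalised counts in the knockout-labelled libraries. Against a floor of 3 reads in wild type they were at least 47.1-fold, 82.1-fold and 46.2-fold higher in the lower of the knockout-labelled libraries. The genes that fell were Eno1b, an enolase gene copy (ENSMUSG00000059040, chromosome 18, 48045335 to 48048378), from 3789 to 56 and 280.4, Rpl26, a ribosomal protein gene (ENSMUSG00000060938, chromosome 11, 68901583 to 68906989), from 20654 to 2778 and 554, and Fam25c (ENSMUSG00000043681, chromosome 14, 34351881 to 34355433), from 7458 to 1025 and 701.

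These 5 higher and 3 lower genes were the ones past an adjusted p of 0.05 among 17122 tested in edgeR's quasi-likelihood test of 2 knockout-labelled libraries against 1 wild-type-labelled library. Their adjusted p-values in edgeR were 0.00352 for Krt80 and Eno1b, 0.00473 for Echdc1, 0.00749 for Tdg and Gca, 0.00955 for Fam25c, 0.0199 for Rpl26 and 0.0292 for Bdkrb2, and both knockout-labelled libraries lay on the same side of wild type for all 8. Eno1b, Rpl26 and Tdg have near-identical copies elsewhere in the genome, and how the reads were divided between copies is uncertain; Eno1, the main enolase gene, chosen after its values were seen, was at 47453 in the knockout-labelled mean and 42713 in the wild-type-labelled library. With each library's trend on gene length as an offset, Fam25c was no longer called by edgeR. Taking knockout-labelled library 2 as the lone library in place of wild type gave 213 calls, and taking library 1 gave 2.

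The authors' deposited table, which has adjusted p-values of its own for 10718 genes, put 15 genes higher and 4 lower at an adjusted p under 0.05. In the authors' deposited table these included all of the genes above except Bdkrb2 (adjusted p = 0.0648). The authors' deposited table also called Pkp1 and Pard6b, of lists described later. From the rest of its calls, chosen after their values were seen, Peg10, an imprinted gene derived from a retrotransposon, was at 17266 normalised counts against 2209. Map3k1, a kinase upstream of JNK, was at 1754 against 357, Hr, a nuclear receptor corepressor, at 2362 against 479.8, and Wee1, a kinase that restrains entry into mitosis, at 325 and 929.9 against 44. Mt1, a metallothionein, was at 2349 against 9849.6. In edgeR's test the adjusted p-values of Peg10, Map3k1, Hr, Wee1 and Mt1 were 0.113, 0.239, 0.241, 0.113 and 0.237, so none passed there.

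By size alone, 3058 genes were at least 2-fold higher and 2798 at least 2-fold lower in the knockout-labelled mean among 16408 genes with a summed value of at least 10. Among 16316 genes with recovered reads, 5323 (32.6%) were at least 2-fold from wild type with library 1 alone and 7142 (43.8%) with library 2 alone. The knockout-labelled libraries differed from each other about as much as library 1 did from wild type. There 2922 genes were at least 2-fold higher and 2402 lower in library 1 than in library 2, or 32.6%. In simulated libraries of this design, with the common dispersion for every gene, 45.5% of the unchanged genes passed the size rule. That is above the 35.7% of all genes that passed in the data. The simulation therefore overstated the spread, and its share is not the false positive rate of the rule here. Genes at least 2-fold from wild type on the same side in both knockout-labelled libraries numbered 1502 higher and 1772 lower. Library 2 was at least 2-fold from both others on the same side for 3202 genes and library 1 for 1851, against 3274 for the wild-type-labelled library. Scaling to total counts shifted all log2 ratios by 0.21 and gave 3823 higher and 2201 lower, and scaling without the 20 most abundant genes shifted them by 0.20.

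Among the genes with the largest ratios, Six4, a homeobox factor, stood at 126 and 214 normalised counts in the knockout-labelled libraries and Card14, a scaffold of NF-kB signalling in epithelia, at 118 and 214, each with 0 reads in the wild-type-labelled library. Lancl3, Lrrc2, Zfp697, Bend4, Cacna1c and Dtna also had 0 reads there. Lancl3 was at 34.1 and 375 in the knockout-labelled libraries, Lrrc2 at 205 and 128, Zfp697 at 99.6 and 159.7, Bend4 at 85.3 and 141, Cacna1c at 102 and 107 and Dtna at 74.9 and 133. In the other direction, Fam178b, Plcxd1, the defensin gene Defb50 and the linker histone gene Hist1h1a had 0 reads in both knockout-labelled libraries and 114, 113, 113 and 105 normalised counts in wild type. Against a floor of 3 reads over the knockout-labelled pair, these were at least 78.2-fold, 77.5-fold, 77.5-fold and 71.7-fold lower. Thrsp, a regulator of lipogenesis, was at 19 and 5.84 against 324, and Bmyc, a Myc family member, at 3.79 and 13.6 against 236. None of these passed edgeR's adjusted threshold.

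Gene lists fixed before the data were examined were then compared with random lists matched on expression. Of 34 lists, 9 stood apart, with a median in the lowest or highest 2.5% of the random lists. By the same rule, chosen for this pair after seeing the data, 17 lists stood apart between the knockout-labelled libraries themselves. The random lists treat genes as independent, so standing apart does not show a difference beyond the spread between libraries. The antimicrobial and developmental factor lists were the 2 that stood apart with each knockout-labelled library alone, both set against the same wild-type-labelled library. No member of the 34 lists passed edgeR's adjusted p of 0.05 over all genes tested, while 71 of 672 members had an unadjusted p under 0.05 and 2, Pkp1 and Pard6b, passed the adjusted threshold in DESeq2 with a normal prior. Adjusted over the list alone, edgeR called Krt16, Pkp1, Dsg3 and Tgm1 of the squamous list, Ang, Rnase4 and Pglyrp1 of the antimicrobial list, Cidec and Cidea of the adipocyte list, and Pard6b, Pf4, Ifi27l2a, H2-Aa, Idi1 and Mgp of 6 others. Pglyrp1 was named after its values were seen. Each list was adjusted by itself and not across the 34 lists, so these calls carry no error rate over the lists together. Unadjusted p-values under 0.05 were not particular to list members, and their number over all genes tested is given later. Log2 ratios of the knockout-labelled mean over the wild-type-labelled library also followed a trend on gene length. Spearman rho between log2 ratio and length was 0.40 across 12480 genes (genes are not independent replicates). The median was −0.51 in the shortest genes and 0.45 in the longest (outer quartiles of length). A ratio cannot tell which library carries the trend. Between the knockout-labelled libraries rho was −0.30.

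**Figure D2:**
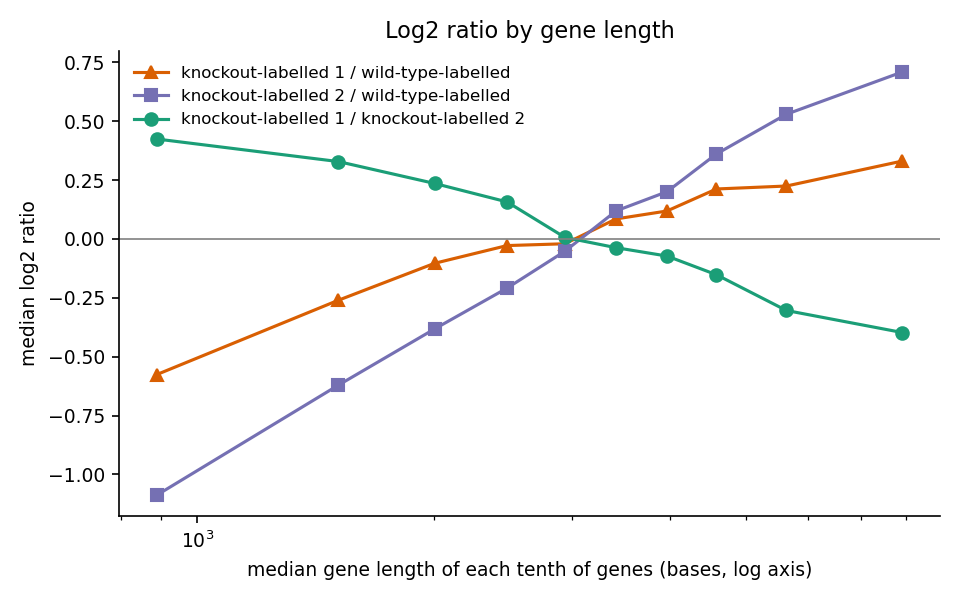
Median log2 ratio (vertical axis) of genes binned by length in deciles against the median gene length of each bin in bases (horizontal log axis), for each knockout-labelled library over the wild-type-labelled library and for the knockout-labelled libraries over each other. Ratios to wild type went up with length for both libraries, with a Spearman rho of 0.28 for library 1 and 0.44 for library 2.

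Antimicrobial and acute-phase genes were lower in the knockout-labelled libraries. Of 23 measured members, 15 were at least 1.5-fold lower and 5 at least 1.5-fold higher in the mean, and 13 were lower in both libraries. Lcn2, which sequesters bacterial siderophores, stood at 32.2 and 10.7 normalised counts against 198, and S100a8, a subunit of calprotectin, at 32.2 and 1.95 against 128; both genes are in the neutrophil list too. Ang and Rnase4, secreted ribonucleases with antibacterial activity, were at 149.8 and 49.7 against 656 and 911 and 1282 against 3923, and Wfdc2, a secreted whey-acidic-domain protein, at 27852 and 7692 against 58503. The genes Ang and Rnase4 overlap and have the same start (chromosome 14, 51091077), so they are not independent members, here or among the calls adjusted over the list. Steap4, a metalloreductase, went the other way at 49.5 against 4.19. The list median lay −1.08 (log2) from that of all genes, at percentile 0.02 of the random lists, and at 0.135 and 0.01 with library 1 and library 2 alone. Between the knockout-labelled libraries the list median differed by more, 1.37 higher in library 1 than in library 2. With the length trend removed the list was at 0.18. Macrophage markers were lower as well, at percentile 0.7. Neutrophil markers, with 8 of 24 higher and 11 lower, were at 28.7 in the mean, 39.6 with library 1 alone and 0.02 with library 2 alone.

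Cell cycle genes were also lower. Of 28 proliferation genes, 14 were at least 1.5-fold lower in the mean, while 8 were lower and 0 higher in both libraries. Among the 14 were Mki67, the proliferation antigen, at 1445 and 823 normalised counts against 3132, Birc5, the mitotic protein survivin, at 439 and 499 against 1524, and the mitotic cyclin gene Ccnb2 at 278 and 284 against 881. Ube2c, Aurkb and Bub1b, which act in mitosis, were at 897 and 457 against 1925, 287 and 417 against 803 and 248 and 563 against 812. The replication genes Pcna and Rrm2 did not share the direction, at 7821 against 5475 and 4299 against 2953, and the 2 members at least 1.5-fold higher were Kif20a and Mcm5, named after their values were seen and both below wild type with library 1 alone. The list median lay −0.63 from all genes, at percentile 0.02. With library 2 alone it was at 7.53 and no longer stood apart. The 7 cyclin-dependent kinase inhibitors were at percentile 21.3, or 56.7 with the length trend removed, the median turning from −0.27 to 0.030. Cdkn2a, a classical Polycomb target, was at 992 and 586 against 326, whereas Cdkn2b, close to it on chromosome 4, was lower at 1040 and 741 against 1181. Cdkn2c was at 274 and 440.1 against 721, and Cdkn2d at 239.9 and 109 against 402.

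Developmental transcription factors, many of which are silenced by PRC2 in adult tissues, were higher as a list at low levels. Of 58 measured factors outside the Hox clusters, 29 were at least 1.5-fold higher and 12 at least 1.5-fold lower in the mean. In both libraries 16 were higher and 7 lower. En2, Pax7, Otx1, Foxl2 and Gata4 had 0 reads in the wild-type-labelled library. En2 was at 60.7 and 94.5 normalised counts in the knockout-labelled libraries, Pax7 at 42.7 and 81.8, Otx1 at 24.7 and 41.9, Foxl2 at 19.9 and 45.8 and Gata4 at 20.9 and 39.9, at least 19.3-fold higher for En2 and 6.64-fold for Gata4 in the lower library against the 3-read floor. Tbx2 and Tbx3, the most abundant members, were at 4017 against 4571 and 4334 against 3989. The list median lay 0.54 from all genes, at percentile 97.78 and close to the limit. It was at 91.5 with the length trend removed and at 95.8 with genes of a summed value of 1 or more included. Hox genes did not stand apart, with 6 of 30 higher and 9 lower (percentile 7.66). Hoxa9 was at 1244 against 1805 and Hoxa10 at 1472 against 1214, Hoxc6 was at 36 and 13.6 against 0, and Hoxd4 at 11.4 and 0 against 29.3. With library 1 alone the Hox median lay at percentile 72.0 and with library 2 alone at 1.52, on opposite sides of all genes. The PRC2 subunits were at percentile 93.5, with 5 of 14 at least 1.5-fold higher, including Lcor at 139.8 against 40.9 and Phf19 at 62.6 and 97.4 against 35.6. With library 1 alone that list was at 97.85 and with library 2 alone at 91.8.

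In the urothelium, markers of the superficial layer and markers of the basal layer were compared separately. The uroplakin genes Upk2 and Upk3a, which encode the plaque proteins of umbrella cells, were at 2925 and 1398 normalised counts against 6204 and at 3144 and 2005 against 6943. Psca was at 3520.3 against 8914 and Sprr2a3, whose reads may be shared with close copies, at 17354 against 58119, while the abundant keratin Krt7 was at 162011 against 174374. Of 23 superficial markers 8 were at least 1.5-fold lower and 3 higher, and the list did not stand apart (median −0.33, percentile 21.9). Over the 18 markers with recovered reads, which leave out abundant genes such as Krt7 (an alternative chosen after seeing the data), the mean lay at 6.88, library 1 alone at 0.62 and library 2 alone at 2.97. With the length trend removed the median of all 23 turned to 0.19. Of 17 basal markers 5 were higher and 1 lower (percentile 95.3). Trp63, the master regulator of basal cells, stood at 2470.3 and 6005 against 2155, Krt14 at 18858 and 10238 against 8076, and Krt5 at 171281 against 142909. With library 1 alone the basal list was at 99.48 (median 0.45) and with library 2 alone at 49.3 (median −0.18).

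Genes of cell junctions were higher in the mean, and so were those of squamous differentiation, though not once members without recovered reads were left out. Of 20 squamous genes 10 were at least 1.5-fold higher and 5 lower. Pkp1, a desmosomal plaque protein, was at 2099 and 2855 normalised counts against 512, Tgm1, which crosslinks the cornified envelope, at 2931 and 1602 against 589.7, the desmosomal cadherin gene Dsg3 at 115 and 131 against 2.09, and the keratin gene Krt16 at 109 and 103 against 0. Sprr1a, a cornified envelope precursor, was lower at 74721 against 159707. The squamous median lay 0.48 from all genes (percentile 98.46). Without Sprr1a, Krt4 and Krt6a, whose reads per library could not be recovered, an alternative chosen after seeing the data, the mean of the other 17 genes lay at percentile 65.6, library 1 alone at 98.03 and library 2 alone at 53.8. Krt4 and Krt6a, named after their values were seen, were at 29737 against 15818 and 22467 against 6652. Of 20 junction genes 9 were higher and 1, Cldn7, was lower, named after its value was seen. Pard6b and Pard3, polarity proteins of the tight junction, were at 1702 and 1036 against 235 and 2649 and 4382 against 1546. The tight junction scaffold gene Tjp1 was at 5534 and 8348 against 2189, and Cgn at 3994 and 6857 against 2559. The junction median lay 0.44 from all genes, at percentile 99.7, with library 1 alone at 99.95 and library 2 alone at 80.0.

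Inflammatory mediators lay on both sides of the wild-type level. Il33, an epithelial alarmin, was at 5619 and 8016 normalised counts against 1925, and Il1rn, the interleukin-1 receptor antagonist, at 2028 against 1194. Csf3, the neutrophil growth factor, was at 5.69 and 0 against 41.9, and Tnf had 0 reads in both knockout-labelled libraries against 26.2. The 14 cytokines lay at percentile 26.8 (6 higher, 5 lower), and their median, −0.27, turned to 0.12 with a minimum sum of 1, 0.22 with a minimum sum of 50 and 0.13 with the length trend removed. The 25 chemokines lay at 38.7 (7 higher, 10 lower; median −0.10, or 0.45 with the length trend removed), with the neutrophil attractant Cxcl5 at 174 and 36 against 6.28, and the platelet factor gene Pf4 at 575 and 401 against 1906. The 30 NF-kB targets lay at 90.7 (11 higher, 4 lower), with the kinase gene Map3k8 at 154 and 176 against 30.4. The 30 bacterial sensors lay at 32.9 (8 higher, 7 lower), with Casp4, a sensor of cytosolic lipopolysaccharide, at 50.3 and 31.2 against 261, and Pycard, the inflammasome adaptor, at 1499 and 2798 against 5726. With library 1 and library 2 alone the cytokines were at percentiles 85.3 and 2.38 and the chemokines at 87.3 and 0.04, on opposite sides of all genes, and the NF-kB targets were at 99.26 and 53.1.

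Interferon-stimulated genes lay at percentile 27.9 (8 of 32 higher, 11 lower), with Ifi27l2a at 141 and 128 normalised counts against 875, and Bst2, the antiviral factor tetherin, at 777 and 465 against 1794. With library 1 alone this list lay at 7.42 and with library 2 alone below every one of the 10000 random lists. Genes of MHC class II presentation were at percentile 4.37, inside the limits, with 6 of 9 lower, among them H2-Aa at 101 and 46.7 against 443 and Cd74, the invariant chain, at 463 and 690.4 against 935. With the log2 fold changes of the authors' deposited table that list was at 0.4. Prostaglandin genes lay at 46.9 (3 of 14 higher, 4 lower), with Ptges, a prostaglandin E synthase, at 3798 and 2153 against 5377.

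Markers of other mucosal cell types were examined as a description of what the samples held. Macrophage genes were lower: 14 of 26 monocyte and macrophage markers were at least 1.5-fold lower and 2, Mrc1 and Ccr2, were higher, the former named after its value was seen. The complement genes C1qb and C1qc were at 526 and 519 normalised counts against 1730.5 and at 183 and 345 against 744, and Folr2, a marker of resident macrophages, at 35.1 and 37 against 181. The macrophage median lay −0.66 from all genes (percentile 0.7), with library 1 alone at 0.56 and library 2 alone at 5.04. Neutrophil markers were at percentile 28.7 (8 of 24 higher, 11 lower), and at 39.6 with library 1 and 0.02 with library 2 alone. That list mixed directions, with 10 markers lower and 3 higher in both libraries. Stfa3, Lcn2, S100a8 and Retnlg, its named members with the largest ratios, were lower in both, Stfa3 at 2.84 and 0 against 35.6 and Retnlg at 22.8 and 0 against 72.3. Its most abundant members, Padi4 and Gcnt2, were higher, at 1355 and 2149 against 914 and at 780 and 432 against 323. The lists of dendritic cells (percentile 19.4, 3 of 10 higher and 4 lower), lymphocytes (23.9, 1 of 9 and 3, with a median of −0.53 that turned to 0.24 with a minimum sum of 1) and mast cells and eosinophils (44.6, 4 of 9 and 4) did not stand apart. Nor did those of smooth muscle (72.7, 4 of 16 higher and 0 lower), nerve and glia (45.6, 5 of 17 and 3) and erythrocytes (44.96, 2 of 7 and 3). Clec10a, of some dendritic cells, was at 4.74 and 68.2 against 270.3, and Sox10, of Schwann cells, at 7.59 and 0.974 against 53.4.

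The fibroblast list was at percentile 55.4 (4 of 24 higher, 6 lower), with the matrix genes Mgp at 2513 and 1770.2 normalised counts against 7984 and Dcn at 9405 and 6018 against 19469.8, but Col1a2 at 27151 against 26848; with the length trend removed the list was at 1.44. Endothelial genes lay at 24.7 (5 of 20 higher, 7 lower), with the adhesion molecule genes Selp at 52.2 and 196 against 10.5 and Sele at 56.9 and 195 against 22, and Emcn at 618 and 630.0 against 1586. With library 1 alone the endothelial list was at 0.68 and with library 2 alone at 55.6, on opposite sides of all genes. Adipocyte genes were higher (6 of 10), by a median of 2.71 (percentile 100), or 1.84 with genes at 0 set to their bound. This rested on library 1: the lipid droplet genes Cidec and Plin1 stood at 148 and 74 in library 1, 31.2 and 0 in library 2 and 0 in wild type, Cfd at 528, 9.74 and 126, below wild type in library 2, and with library 2 alone the list was at percentile 62.6. Fabp4, the 1 member at least 1.5-fold lower, was at 16541 and 8222 against 24148, with a log2 ratio of 0.0064 once the length trend was removed.

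Glycolytic and hypoxia-responsive genes were higher in the mean, with 8 of 23 at least 1.5-fold higher and 0 lower. Car9, a carbonic anhydrase induced by hypoxia, was at 80.6 and 106 normalised counts against 20.9, Pfkfb3, an activator of glycolysis, at 403 and 457 against 113, Egln3, an oxygen sensor, at 1795 and 2299 against 1011, and Hk1, a hexokinase, at 9425 and 15069 against 6197. Gapdh was at 75992 against 86126, below wild type as deposited and slightly above it with scaling to total counts. The list median lay 0.31 from all genes (percentile 98.37), and did not stand apart with library 2 alone (87.7). Sterol synthesis genes were at percentile 96.0 (7 of 22 higher, 3 lower), with Idi1 at 418 and 971 against 101 and Hmgcs1 at 5799.8 and 9592 against 3409.6, and at 23.1 with library 1 and 99.52 with library 2 alone, on opposite sides of all genes. The list of epithelial-mesenchymal transition and matrix remodelling was at 17.7 (4 of 27 higher, 7 lower), with the matrix metalloproteinase genes Mmp3 at 231 and 243 against 737 and Mmp10 at 550.0 and 440.1 against 1476.

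Lists that describe sample quality differed between libraries as well. Of 11 mitochondrially encoded genes 10 were at least 1.5-fold lower and 1, mt-Nd3, was higher, with mt-Co1 at 8572 and 10002 normalised counts against 24881 and mt-Nd1 at 5695 and 5746 against 13420.5. Their share of all counts was 0.110% in the knockout-labelled column and 0.217% in the wild-type-labelled one, and the list was at percentile 1.21, or 12.97 against random lists matched on gene length as well. Stress and immediate-early genes were at 62.6 in the mean, but on opposite sides in the knockout-labelled libraries, at 99.81 in library 1 and 0.1 in library 2, with Klf6 at 9810.2 and 4405 against 7268 and Ddit3, of the unfolded protein response, at 895 and 281 against 1039. The list of X- and Y-linked genes was at percentile 63.2. Although the labels give female mucosa, all 3 libraries held reads of Y-linked genes, with Ddx3y at 1269.6 normalised counts in the wild-type-labelled library and 1053 and 1172 in the knockout-labelled libraries. Xist, which is expressed from the inactive X chromosome of female cells and was named after its values were seen, was at 49.2, 27.5 and 61.3.

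**Figure D3:**
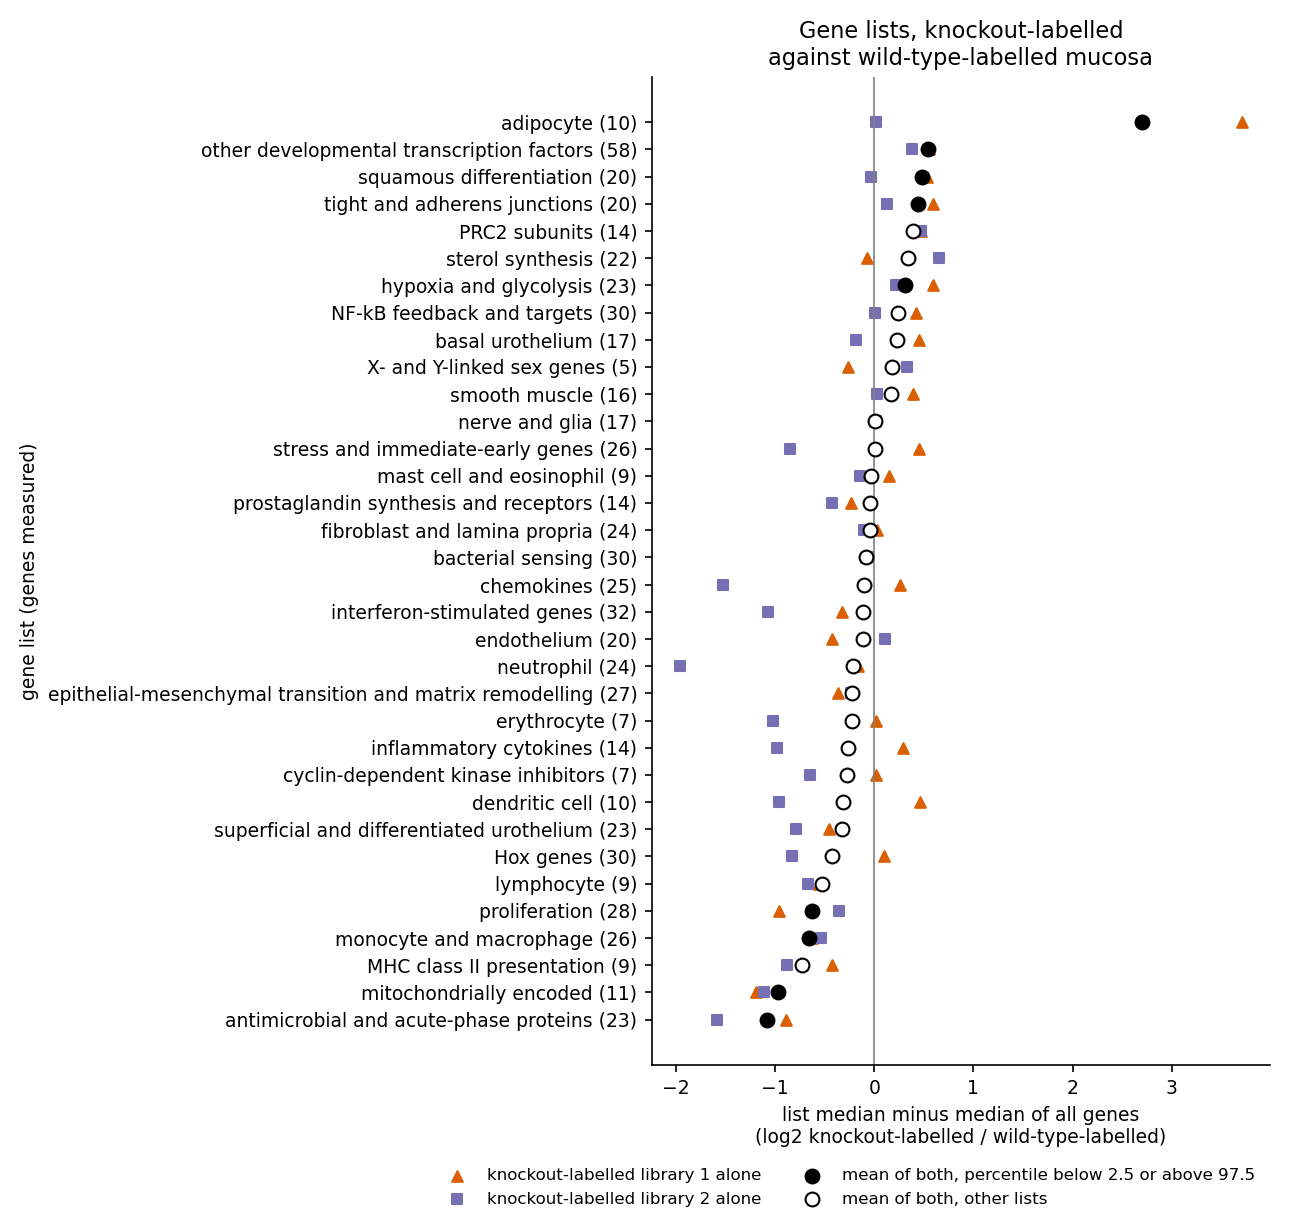
Median log2 ratio of each of 34 gene lists minus the median of all genes (horizontal axis), with lists on the vertical axis and their number of measured genes in brackets. Circles give the mean of the knockout-labelled libraries, filled for the 9 lists in the lowest or highest 2.5% of matched random lists, and triangles and squares give library 1 and library 2 alone. The antimicrobial median lay at −1.08 in the mean, −0.89 with library 1 and −1.59 with library 2, whereas the neutrophil medians were −0.16 and −1.96.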

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

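Tests on the recovered libraries and the removal of the length trend were chosen after seeing the data. The wild-type-labelled group had 1 library, so its own spread was not measured, and edgeR's simulated power was low for genes changed 4-fold. No paired analysis was possible because each genotype had 1 labelled sample and the recovered libraries carry no replicate numbers. Where a value changed, the cause was not tested unless the alternative's own construction shows it. The Eed log2 ratio, −0.27, stayed below 0 in all settings and was −0.054 with scaling to total counts, −0.068 without the 20 most abundant genes, −0.0080 with the length trend removed, and between −0.546 (library 1 alone) and −0.031 (library 2 alone). The 3058 higher and 2798 lower genes became 627 and 477 with the authors' log2 fold changes, which are shrunken, 1828 and 1951 with a minimum sum of 50, 1502 and 1772 with both libraries past the rule, 5 and 3 by edgeR, 5 and 2 by edgeR with a length offset, and 40 and 7 by DESeq2 without a prior. Lower genes outnumbered higher ones by the size rule with the minimum of 50, with upper quartile scaling (2790 higher, 3101 lower), with both libraries past the rule and with library 1 alone (2504 and 2819) or library 2 alone (3193 and 3949). With a minimum of 1 read edgeR gave 38 and 13, and with upper quartile scaling 10 and 4; unadjusted p-values under 0.05 numbered 1337 in edgeR's main test.

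Of the list percentiles, squamous differentiation went to 65.6 over the genes with recovered reads, 65.5 with thinned reads, which also need recovered reads, 91.0 with the authors' log2 fold changes, 78.5 with a minimum sum of 50 and 96.1 with unmatched random lists. Hypoxia and glycolysis went to 94.5 with the authors' values, 96.8 with the minimum of 50 and 88.1 unmatched, adipocyte genes to 92.8 and 68.4 with the authors' values and the minimum of 50, and junctions to 94.5 unmatched. MHC class II went to 0.4 with the authors' values. Developmental factors went to 95.8 with a minimum sum of 1, 97.0 with protein-coding genes, 97.0 matched on length and 91.5 with the length trend removed. Mitochondrial genes went to 12.97 matched on length and 7.41 with the trend removed, and fibroblast genes to 1.44 with it removed. With each knockout-labelled library alone, over the genes with recovered reads, the percentiles ranged from 1.52 to 72.0 for Hox genes, 0 to 7.53 for proliferation, 53.8 to 98.0 for squamous differentiation, 80.0 to 99.95 for junctions, 2.38 to 85.3 for cytokines, 0.04 to 87.3 for chemokines, 0 to 7.42 for interferon-stimulated genes, and 23.1 to 99.5 for sterol synthesis. They ranged from 87.7 to 99.98 for hypoxia and glycolysis, 0.1 to 99.8 for stress genes, 0.02 to 39.6 for neutrophils, 0.56 to 5.04 for macrophages, 62.6 to 100 for adipocytes, 0.025 to 3.44 for mitochondrial genes, 91.8 to 97.9 for PRC2 subunits, 0.62 to 2.97 for superficial urothelium, 49.3 to 99.5 for basal urothelium, 53.1 to 99.3 for NF-kB targets and 0.68 to 55.6 for endothelium. Between those libraries the median minus that of all genes changed sign for the lists of squamous differentiation, Hox genes, cyclin-dependent kinase inhibitors, basal urothelium, cytokines, chemokines, sterol synthesis, stress genes, dendritic cells, mast cells and eosinophils, fibroblasts, endothelium, erythrocytes and sex-linked genes. Without leaving out a library, a list median changed sign for cytokines (−0.27) with a minimum sum of 1 (0.12) or 50 (0.22) and with the length trend removed (0.13), for lymphocytes (−0.53) with the minimum of 1 (0.24), and with the length trend removed for cyclin-dependent kinase inhibitors (0.030), superficial urothelium (0.19), chemokines (0.45) and sex-linked genes (−0.17); the medians of stress genes and of nerve and glia, near 0, changed sign in several settings. The remaining 570 list percentiles under alternatives kept their side of the limits. The antimicrobial list stood apart in every setting run. For named genes, 1546 log2 ratios under alternatives moved by less than their counting interval, and 551 moved by more. Of named genes at least 1.5-fold from wild type in the mean, log2 ratios changed sign between libraries alone for Kif20a (−0.74 to 1.51), Mcm5 (−0.042 to 1.25), Cfd (−3.56 to 2.06) and Hba-a1 (−4.17 to 0.014); of the other named genes they did so for Ezh2 (−0.309 to 0.602), Klf6 (−0.722 to 0.433), Kdm5d (−0.640 to 1.01) and Xist (−0.818 to 0.312). Plin1 ranged from 0 to 6.23, and with the length trend removed Fabp4 was at 0.0064 and Hba-a1 at 0.029.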

Other observations

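Reads of genes for secreted liver proteins, chosen after their values were seen, were present in all 3 libraries, and their source was not tested. Alb, which encodes serum albumin, stood at 972 normalised counts in the wild-type-labelled library, 25.6 in knockout-labelled library 1 and 529.7 in library 2, and Ahsg, which encodes fetuin-A, at 281, 3.79 and 255. Ttr, the thyroxine carrier, was at 196, 4.74 and 105. The globin gene Hba-a1, whose reads are hard to tell from those of its copy, was at 8895, 8983 and 495.

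The tests of the length trend, of neutrophil number, of the spread between libraries and of admixed male cells were chosen after the results they bear on were seen. Genes with 0 reads in the wild-type-labelled library and many in both knockout-labelled libraries, such as Echdc1, Gca and En2, form the first pattern. At 50 or more normalised counts in both other libraries, 31 genes were at 0 in the wild-type-labelled library alone, 4 in library 1 alone and 46 in library 2 alone. The wild-type number was 0.6739 times the larger of the other numbers, between the bounds set for random loss of transcripts in 1 library, which therefore stays open. Release of silenced genes on loss of Eed predicts more developmental factors among the wild-type zeros: 5 of 149 genes at 20 or more were such factors, against 4 of 181 for library 2 and 0 of 70 for library 1 (Fisher's exact test across genes, two-sided, p = 0.303). These explanations cannot be told apart with 1 wild-type-labelled library.

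The lower antimicrobial and proliferation lists and the higher junction list form the second pattern. A trend on gene length as the whole cause is argued against, since with the trend removed the medians went from −1.08 to −0.74, from −0.63 to −0.62 and from 0.44 to 0.50, and the 3 lists stayed outside the limits, the nearest to the middle at percentile 0.18. Fewer neutrophils as the whole cause of the lower antimicrobial list stay open. Without members that another list holds, the list's median was −0.87 (percentile 0.27). That cannot decide, because members that neutrophils can also express, such as Pglyrp1, remain in the list. With library 1 alone the antimicrobial list was at 0.135 and neutrophil markers at 39.6, and with library 2 alone neutrophil markers were at 0.02. Of 24 neutrophil markers, 10 were at least 1.5-fold lower in both libraries and 3 higher in both. The percentile of 39.6 therefore covers markers on both sides and cannot show that neutrophil number was unchanged with library 1. The spread between libraries of 1 genotype label may account for the antimicrobial and junction lists, whose medians differed between the knockout-labelled libraries by 1.267 and 1.137 times the difference of their mean from wild type, and stays open for the proliferation list, at 0.8195 times with a single pair to judge by. A deviating wild-type-labelled library, which these comparisons share, fewer macrophages, whose markers were at percentile 0.7, a lower antimicrobial response in mucosa labelled Eed knockout, a different stage of infection and a difference between mice all stay open as hypotheses, untested with these libraries.

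Reads of Y-linked genes in libraries labelled female form the third pattern. Ddx3y, Eif2s3y, Kdm5d and Uty together had 3399 normalised counts in the wild-type-labelled library, 3499 in library 1 and 4012 in library 2. A small share of male cells in female tissue is argued against, since Xist was at most 1.529% of that sum. Male tissue in all libraries predicted, in a bound set before the values were seen, that each Y-linked gene would reach 10% of its X-linked partner, and it was missed by Ddx3y in library 1 (8.397% of Ddx3x) and library 2 (7.384%) and by Kdm5d in library 1 (8.771% of Kdm5c). That bound was judged too strict only after it had been missed, because Ddx3y varied 1.21-fold between libraries and Ddx3x 2.33-fold. The Kdm5d value also has an exact 95% counting interval of 7.40% to 10.3%, although Kdm5d itself varied 3.15-fold. Eif2s3y was at 204.9%, 128.3% and 61.3% of Eif2s3x in the wild-type-labelled library, library 1 and library 2. Uty was at 107.6%, 66.4% and 60.6% of Kdm6a. With the low Xist, these values argue against mainly female tissue in all 3 libraries. Male tissue, or a label that gives the wrong sex, may still be the source and stays open, since its own bound was missed.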
